A study of Mus musculus with 16 samples.

How the data were processed

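The series holds 16 samples of mouse mammary gland. RNA was sequenced in 7 of them, 4 wild type and 3 Socs2-Δs, all at day 13 of pregnancy. Per the labels' protocols, poly(A) RNA was purified with Trizol and a column kit, and libraries were made with a TruSeq RNA kit. The submitters' processing notes name CASAVA, Bowtie2, STAR and DESeq2, without versions or roles, and the mouse build mm9. The annotation release and any filter are not given in the sources used here. The authors deposited FPKM, that is reads per kilobase of gene and scaled to library size, in a table of 24187 rows with a gene symbol and an Entrez ID. The 9 ChIP-seq and DNase-seq samples were not analysed here.

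Libraries were grouped by their titles. The genotype tag of the 3 mutant RNA samples reads wild type, which conflicts with their titles and source names. Each column of the table was assigned by its group and replicate number. Of the Entrez IDs, 24107 were found in a RefSeq gene table of the assembly GRCm38.p6, which was used for names and gene order only. It gave symbols for 12 rows without a name and for 27 rows in which a spreadsheet had turned the name into a date. A value of 0 in all libraries was listed for 3143 rows.

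Depth was taken from the values. For each gene the FPKM of the 7 libraries were divided by the relative worth of 1 read in each library, found from low genes, and the largest step was sought of which all values were whole multiples within 0.02. This solved 21044 of 21044 rows above 0, up to a factor common to the libraries of a gene. On simulated reads with known answers the step was exact for 95.7% of rows, so totals are slightly low where a common factor was missed. The totals were 21.3 to 24.5 M (mega) reads per library. The product of total reads and the worth of 1 read varied between libraries from 0.851 to 1.171 of its mean, so the deposited values were not scaled to equal totals. Median-of-ratios factors of the FPKM, over genes above 1 in all libraries, were 0.969 to 1.045. The 50 most abundant genes took 19.9 to 29.9% of the FPKM of a wild-type library and 30.3 to 34.0% of that of a mutant library.

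The test was limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes with a mean-variance trend) on log2(FPKM + 1), for 13392 genes with a mean of at least 1 FPKM over the 7 libraries. No covariate was used, and p was adjusted by Benjamini and Hochberg with a threshold of 0.05. Log2 differences are mutant minus wild type and were computed on log2(FPKM + 1), which understates changes of low genes. For Socs2, an exact two-sided permutation test over the 35 splits into 4 and 3 libraries was added. Values were simulated for these 13392 genes, with 200 of them changed by 1 or 2 on the log2(FPKM + 1) scale. For abundant genes these are 2-fold and 4-fold changes, and for low genes the FPKM differ by more at a rise. The test recovered 38.0% of the changes of 1 and 81.0% of those of 2, and called 5 unchanged genes. A gene that changed by 2-fold could thus often be missed with these libraries. Each gene was given the same spread in all libraries, so a joint departure of some libraries was not simulated. In the simulation a list shifted by 1 on the log2 scale was called, and 0 of 36 unshifted lists were. The genes were simulated independently and the lists drawn at random, so false calls of lists whose genes vary together could not appear. The estimated correlation was 0.576 for the real milk protein list. Without a stated use of strand in the counting, overlapping and antisense genes cannot be told apart, and the caseins, the Klk1b family and ribosomal protein genes with pseudogenes can share reads.

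Before the data were examined, 37 gene lists were written for the signalling pathway, milk synthesis, lipid metabolism, the cell types of the gland, stress and RNA quality. Of their genes, 21 were not found by symbol, some of them older or newer names of genes found under another. The 35 lists with at least 4 tested members were tested with camera at a preset inter-gene correlation of 0.01, and adjusted over the lists; mitochondrially encoded genes and erythroid genes had fewer members. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in one direction, were alternatives. Several lists share genes, the caseins in particular, and are not independent.

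The named genes followed a rule set before the data were examined. It took 14 fixed genes of the pathway, up to 10 rises and 10 falls of largest size among genes past the threshold without overlap of the groups, the 10 smallest p where fewer than 10 passed, up to 4 members of smallest p per list, and the neighbours of Socs2. Predicted genes, clone names, immunoglobulin and T cell receptor segments were left out of all but the first part. The same rule of size was then applied to the comparison without wild-type replicates 3 and 4. That repeat, the transcripts of other tissues, Neat1, Alb, Cd79a, and list members named because 5 or fewer were counted were chosen after the values were seen.

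The alternatives set in advance were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, median-of-ratios and quantile scaling, scaling without the 50 most abundant genes, robust variance, no variance trend, library weights, the replicate number as a block, a log2 difference of at least 1, and each library left out in turn. Added after the data were seen were fits without wild-type replicates 3 and 4, without wild-type replicate 4 and mutant replicate 2, with a term for wild-type replicates 3 and 4, and limma voom on the recovered reads with median-of-ratios library sizes. The first of these compares 2 with 3 libraries. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.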

Results

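The series examined mammary glands of wild-type C57BL/6 mice and of Socs2-Δs mice, a line made by CRISPR/Cas9 genome editing. Socs2 is a cytokine-inducible gene whose product restrains JAK-STAT signalling, and the title of the series names STAT5 as the regulator of interest. The comparison in hand is messenger RNA sequencing of whole mammary gland at day 13 of pregnancy, with 4 wild-type and 3 Socs2-Δs libraries. The values were FPKM per gene for 24187 rows. The steps between low values gave whole reads for each of the 21044 rows above 0 in any library (tolerance 0.02 of a read). The recovered totals were 21.3, 21.5, 24.5 and 21.8 M (mega) reads for wild-type replicates 1 to 4, and 21.8, 22.5 and 22.3 M for mutant replicates 1 to 3. Depth was thus alike in both groups. The genotype tag of the mutant RNA samples reads wild type, whereas their titles and source names read Mut; the libraries were grouped by title. The labels do not say whether replicates were separate animals, so p-values measure the spread between these samples. They state that wild-type mice were purchased, so breeding source and genotype run together.

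Wild-type replicates 3 and 4 stood apart from the other 5 libraries. The first principal component of log2(FPKM + 1), with 61.6% of the variance, placed them at 57.1 and 77.9, against -15.8 and -18.2 for wild-type replicates 1 and 2 and -37.7 to -29.6 for the mutant libraries. The correlation across genes was 0.980 between wild-type replicates 1 and 2 and 0.888 between wild-type replicates 1 and 4. Neat1, a nuclear RNA of paraspeckles, measured 464.1 and 442.2 FPKM in wild-type replicates 1 and 2, 496 to 586 in the mutant libraries, and 11.3 and 14.8 in wild-type replicates 3 and 4. All 72 rows of small nucleolar RNAs with a mean of at least 1 FPKM were lower in wild-type replicates 3 and 4 than in the other 5 libraries, with a median log2 difference of -2.08. Transcripts of salivary gland had a median of 60.5 and 19.4 FPKM in wild-type replicates 3 and 4 and of 0.133 to 0.355 elsewhere. Transcripts of liver had medians of 8.69 and 69.8 FPKM there and of 0.109 to 0.199 elsewhere. Alb, the plasma protein albumin, reached 1137 FPKM in wild-type replicate 4 and 80.9 in replicate 3, against 2.70 to 6.15 in the rest. These lists and genes were chosen after the values were seen. The labels give no batch, and the set of wild-type replicates 3 and 4 holds no mutant library, so a comparison within it could not be made. Values from wild-type replicates 1 and 2 against the 3 mutant libraries are therefore given beside the pooled ones, as a comparison also chosen after the data were seen.

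**Figure D1:**
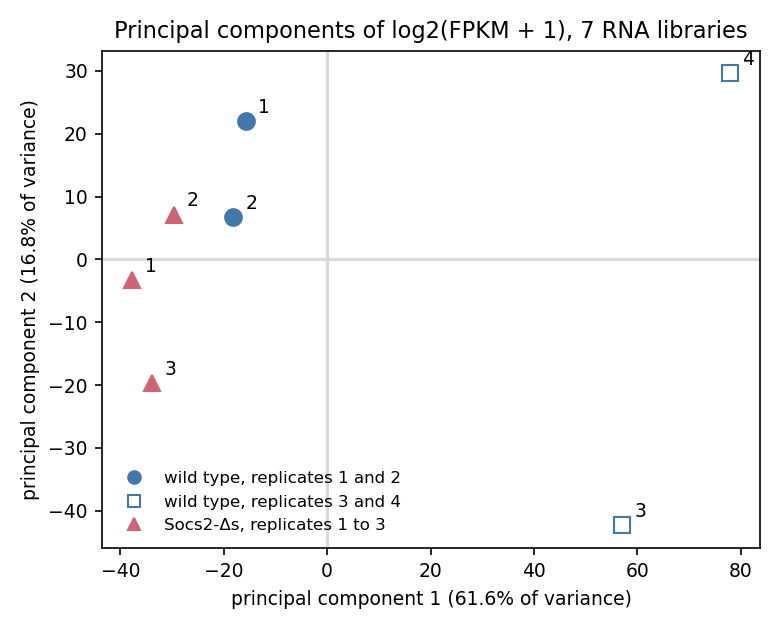
The first 2 principal components of log2(FPKM + 1) over the genes tested, in arbitrary units, with 1 point per RNA library and the replicate number beside it. Wild-type replicates 3 and 4 lie at 57.1 and 77.9 on the horizontal axis, and the other 5 libraries lie between -37.7 and -15.8.

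**Figure D2:**
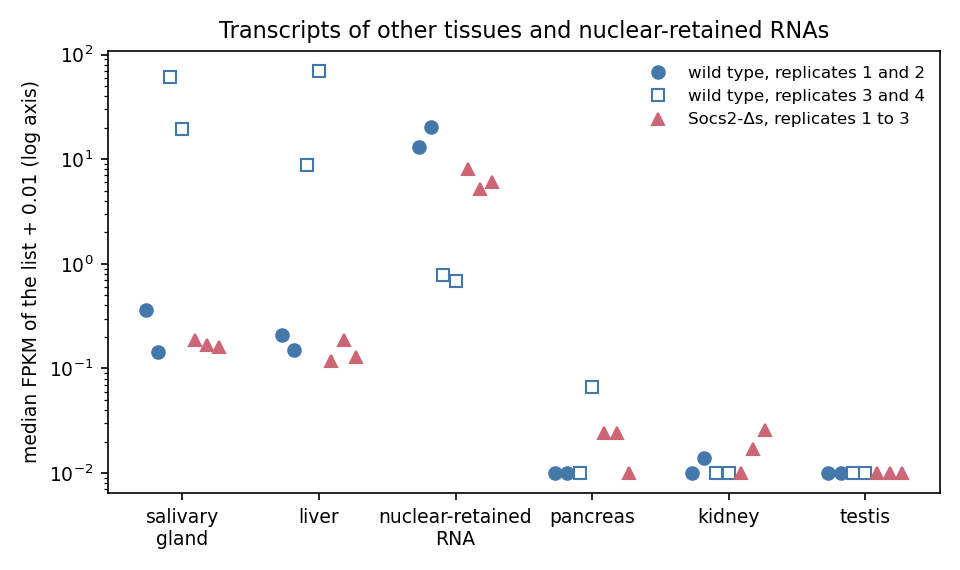
Median FPKM of lists of transcripts of other tissues and of nuclear-retained RNAs, plus 0.01, on a log axis, with 1 point per library. Salivary gland and liver transcripts reach medians of 60.5 and 69.8 FPKM in wild-type replicates 3 and 4 and stay below 0.4 elsewhere, while the medians of pancreas, kidney and testis transcripts stay below 0.1 in all 7 libraries.

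The level of Socs2 itself was compared first, because the line was edited at this gene. Socs2 (Entrez 216233) measured 22.2 ± 4.28 FPKM in wild type (SD, n = 4) and 15.7 ± 1.6 in mutant glands (SD, n = 3), a ratio of 0.71. On the log2(FPKM + 1) scale, which understates changes of low genes, the difference was -0.46 (SE 0.19) and did not pass (limma adjusted p = 0.267). The exact two-sided permutation test over the 35 splits of the 7 libraries gave p = 0.0857, where the smallest possible p was 0.0286. Wild-type replicate 4, at 16.1 FPKM, lay within the range of the mutant libraries (13.9 to 17.1), and the other 3 wild-type libraries lay above it (22.1 to 25.6). Against wild-type replicates 1 and 2 alone, the difference was -0.58 (limma adjusted p = 0.0843). The gene was thus transcribed in every library labelled as mutant, and its lower mean was not separated from the replicate spread. In the order of genes on the assembly GRCm38.p6, the neighbours of Socs2 are Tmcc3, Cep83, Plxnc1 and Cradd on one side and Mrpl42, Ube2n and Nudt4 on the other, with Eea1 farther away. None of these 8 passed. Their log2 differences ran from -0.61 for Mrpl42 to 0.18 for Cep83, and as a list they did not stand out from other genes (camera adjusted p = 0.291).

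Across the gland, 6 of the 13392 genes tested rose in the Socs2-Δs libraries and 0 fell (limma, Benjamini-Hochberg adjusted p under 0.05); at an unadjusted p under 0.05 there were 1222 higher and 1202 lower genes. Gldc, the glycine decarboxylase of the glycine cleavage system, rose from 1.67 ± 0.21 to 8.07 ± 0.50 FPKM (SD, n = 4 and 3; log2 difference 1.77, adjusted p = 0.0240). Rgs8, a regulator of G-protein signalling, showed the largest rise of the 6, from 1.00 ± 1.12 to 19.7 ± 2.56 FPKM (3.51, adjusted p = 0.0356). The other 4 were Oit1 (log2 difference 1.95), the sodium/proton exchanger Slc9a4 (1.78), the potassium channel Kcnk6 (1.48) and the proton/potassium pump Atp12a (2.10), with adjusted p from 0.0250 to 0.0448. Next by p, and not passing, were Xdh (1.83, adjusted p = 0.0666), Hephl1 (1.76, 0.0666), Atp2c2 (2.41, 0.0679) and Mapk4 (2.06, 0.0679). The groups did not overlap for 3019 genes, or 22.5% of those tested, and in 1677 of them the mutant libraries were the higher. For a single gene the chance of no overlap is 5.7% if the 7 libraries are exchangeable, which wild-type replicates 3 and 4 put in doubt. The call rested on single libraries: leaving out wild-type replicate 1 or 2, or mutant replicate 1 or 2, left 0 genes, leaving out mutant replicate 3 left 1 lower gene, and leaving out wild-type replicate 3 or 4 gave 17 or 31. Quantile normalization called 25 higher and 3 lower genes.

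Against wild-type replicates 1 and 2, the same 3 mutant libraries differed in 284 genes, 189 higher and 95 lower, among them all 6 genes above. A fit that kept all 7 libraries, with a term for wild-type replicates 3 and 4, estimates the same differences and called 0 genes. Single genes that pass against wild-type replicates 1 and 2, here and below, thus do so only with the spread of the 5 libraries kept. The genes named here follow the same rule of size, applied after the data were seen. The largest rises were those of Wap, the whey acidic protein of milk (log2 difference 5.59, adjusted p = 0.0110), Glycam1 (4.72), Spp1, which encodes osteopontin (4.56), Fabp3, a fatty acid binding protein (4.26), Rgs8 (3.68), the casein Csn1s2a (3.25), Lao1 (3.0), Rgs16 (2.80), Chrdl2 (2.75) and Lalba, the alpha-lactalbumin of lactose synthesis (2.70). Glycam1 measured 432.7 FPKM in wild-type replicates 1 and 2 and 11379 in mutant glands. The largest falls were those of the lipid droplet gene Cidec (-1.73, from 553.9 to 167.9 FPKM), Rasd1 (-1.61), the ETS factor Etv4 (-1.59), Rab6b (-1.53), Fsd2 (-1.50), Retnla (-1.50), Tusc5 (-1.50), Pck1, the gluconeogenic and glyceroneogenic enzyme (-1.46), Tmem179 (-1.34) and Id4 (-1.33). In this set a further left-out mutant library moved the count to 25, 8 or 66 genes, for replicates 1, 2 and 3. Leaving out wild-type replicate 1 or 2 left a single wild-type library, so that only the mutant libraries supplied the spread, with 2 and 0 genes called. Only Rgs8 among these 20 passed with all 7 libraries, and the limma adjusted p of the other 19 then ran from 0.0761 to 0.557. With all 7 libraries the groups overlapped for Etv4, Rab6b and Pck1, as wild-type replicate 3 lay below every mutant library for these genes.

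Single genes of the STAT5 pathway differed in either direction, and none passed over all genes with 7 libraries. Cish, a feedback inhibitor induced by STAT5, measured 25.8 ± 8.94 FPKM in wild type and 72.2 ± 11.3 in mutant glands (log2 difference 1.51, SE 0.30, adjusted p = 0.122). The kinase gene Pim1 measured 18.3 ± 7.84 and 50.6 ± 2.45 FPKM (1.51, adjusted p = 0.131), and Stat5a 38.7 ± 15.4 and 99.2 ± 8.92 (1.42, adjusted p = 0.143). Stat5b differed by 0.83 (adjusted p = 0.143) and Elf5, the alveolar transcription factor, by 1.30 (adjusted p = 0.249). The libraries of the groups did not overlap for Cish, Pim1, Stat5a and Stat5b. Against wild-type replicates 1 and 2, Cish (1.11, adjusted p = 0.0365), Pim1 (1.0, 0.0371) and Stat5a (0.93, 0.0361) rose, and Stat5b (0.61, 0.0817) and Elf5 (1.24, 0.0709) did not pass. Socs1 (-0.18), Socs3 (-0.10), Bcl6 (-0.14) and the prolactin receptor gene Prlr (-0.08) lay near 0, each within about 1 SE. The list of 19 STAT5 targets shared by many tissues, which holds Cish, Pim1 and Socs2, had no common direction (median -0.14, camera adjusted p = 0.671). Adjusted over the list alone, Cish and Pim1 rose and the cyclin gene Ccnd2 (-1.12) and Igf1 (-1.43) fell. Neither the 8 genes of the SOCS family (median -0.04, camera adjusted p = 0.924) nor the 25 JAK-STAT components (0.12, 0.427) were called. Cish rose in the former when adjusted over the list alone, and Stat5a and Stat5b rose in the latter.

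**Figure D3:**
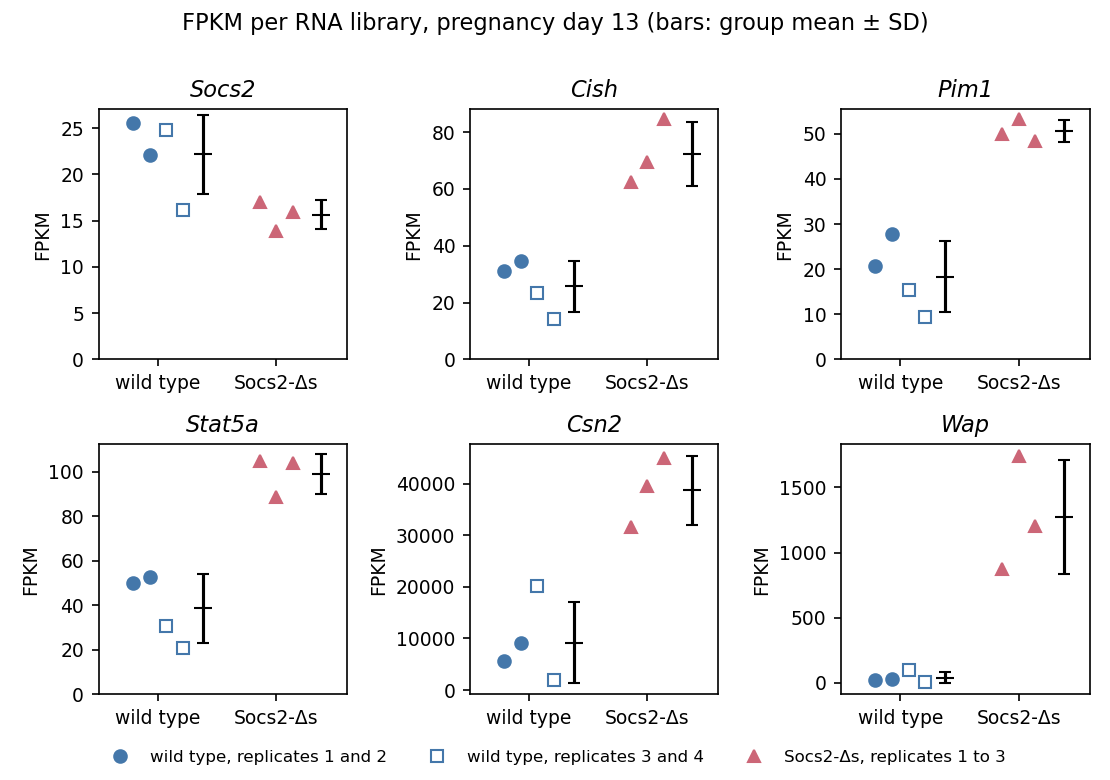
FPKM of Socs2, Cish, Pim1, Stat5a, Csn2 and Wap, on linear axes, with 1 point per RNA library and the group mean ± SD beside the points (n = 4 wild type, n = 3 Socs2-Δs). The mutant libraries lie above all wild-type libraries for Cish, Pim1, Stat5a, Csn2 and Wap, and overlap wild-type replicate 4 for Socs2.

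Milk protein genes were higher in the Socs2-Δs glands as a group. The median log2 difference of the 12 tested members was 2.50, and all 12 were higher (camera adjusted p = 1.45e-09; adjusted p = 0.412 with an estimated correlation). Adjusted over the list alone, 11 of the 12 rose; over all genes 0 passed. Wap measured 39.2 ± 42.0 FPKM in wild type and 1274 ± 438.6 in mutant glands (log2 difference 5.55, adjusted p = 0.0817). Lalba measured 9.01 ± 4.2 and 85.0 ± 36 FPKM, and Glycam1 785.3 ± 784.3 and 11379 ± 2104. Csn2, beta-casein, was the most abundant member at 9183 ± 7841 and 38663 ± 6750 FPKM (2.52, adjusted p = 0.210). Wild-type values of Csn2 ran from 1940 to 20118 FPKM, with wild-type replicate 4 lowest and replicate 3 highest. The median was 2.45 against wild-type replicates 1 and 2 (camera adjusted p = 1.13e-11; adjusted p = 0.513 with an estimated correlation), and 9 of the 12 rose over all genes.

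The list of 22 mammary STAT5 targets, which shares the caseins, Wap, Lalba and Glycam1 with the milk protein list, had a median of 1.75 (camera adjusted p = 3.08e-06; adjusted p = 0.650 with an estimated correlation). Of the 22 genes, 16 rose and Sfrp4, a secreted WNT antagonist, fell (-1.58) when adjusted over the list alone. Cel, a bile-salt activated lipase present in milk, was among the 16, with 8.15 ± 4.79 FPKM in wild type and 40.4 ± 6.48 in mutant glands. The 20 genes of milk secretion had a median of 0.86 (camera adjusted p = 2.26e-05; adjusted p = 0.412 with an estimated correlation), and 11 rose when adjusted over the list alone. Among them Xdh, the xanthine dehydrogenase of milk fat secretion, measured 42.3 ± 9.75 and 150.7 ± 16.0 FPKM, B4galt1, the galactosyltransferase of lactose synthesis, 43.7 ± 11 and 141.4 ± 33.1, and the phosphate transporter Slc34a2 2.80 ± 1.57 and 14.5 ± 1.5. Alveolar secretory markers had a median of 1.49 over 14 genes (camera adjusted p = 2.26e-05; adjusted p = 0.531 with an estimated correlation); adjusted over the list alone, 9 rose, among them kappa-casein Csn3 (686.0 ± 568.3 to 2512 ± 154.2 FPKM), and Aldh1a3, a luminal progenitor marker, fell (-0.81). Over all genes 0 members of these 3 lists passed. The 3 medians were 1.51, 0.85 and 1.29 against wild-type replicates 1 and 2, with 11, 7 and 5 members rising over all genes and 0 falling. Pan-luminal epithelial markers were higher by less, with a median of 0.56 over 16 genes (camera adjusted p = 6.19e-04; adjusted p = 0.735 with an estimated correlation). That median was 0.385 against wild-type replicates 1 and 2 (camera adjusted p = 0.00220; adjusted p = 0.683 with an estimated correlation), as wild-type replicate 4 had a luminal score of -0.932 against -0.155 to 0.048 in the other 3. None of these 16 passed when adjusted over the list alone, and the splicing regulator Esrp2, for example, measured 8.22 ± 4.88 and 24.1 ± 5.01 FPKM.

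Markers of the fat pad and stroma were lower in the Socs2-Δs glands. The 20 adipocyte markers had a median of -0.95, with 19 of 20 lower (camera adjusted p = 3.17e-07; adjusted p = 0.425 with an estimated correlation), and 7 fell when adjusted over the list alone. Cidec, which builds large lipid droplets, measured 560.2 ± 181.2 FPKM in wild type and 167.9 ± 29.1 in mutant glands. Pparg, the adipogenic transcription factor, measured 61.4 ± 18.8 and 27 ± 1.17, and Adipoq, adiponectin, 1262 ± 832.3 and 336.6 ± 59.6. The 17 fibroblast markers had a median of -0.61 (camera adjusted p = 1.18e-05; adjusted p = 0.412 with an estimated correlation), and Dpt, Mfap5, Loxl1 and Pi16 fell when adjusted over the list alone. The 14 macrophage markers had a median of -0.75 (camera adjusted p = 1.36e-06; adjusted p = 0.529 with an estimated correlation), and 11 of them fell when adjusted over the list alone. Cd163, a scavenger receptor, measured 12.2 ± 2.48 and 6.85 ± 1.23 FPKM, and the integrin gene Itgam 5.87 ± 1.53 and 2.89 ± 0.51. Over all genes 0 members of these 3 lists passed with 7 libraries. Against wild-type replicates 1 and 2 the medians were -0.99 for adipocyte, -0.54 for fibroblast and -0.45 for macrophage markers, and Cidec, Adipor2, Pparg and Pck1 fell over all genes. The macrophage score, a mean log2 deviation from each gene's mean over all libraries, was 0.64 and 0.55 in wild-type replicates 3 and 4, -0.06 and 0.08 in wild-type replicates 1 and 2, and -0.55 to -0.23 in the mutant libraries.

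Hormone-sensing luminal markers were lower in the mutant libraries in all 11 tested members, with a median of -0.41 (camera adjusted p = 0.00340; adjusted p = 0.412 with an estimated correlation). Ly6a fell when adjusted over the list alone, from 263.5 ± 113.2 to 91.3 ± 18.0 FPKM. Esr1, the oestrogen receptor, measured 7.79 ± 2.94 and 3.77 ± 0.58 FPKM without passing. The median was -0.47 against wild-type replicates 1 and 2, and Areg, the epidermal growth factor receptor ligand amphiregulin, fell over all genes (-1.26, adjusted p = 0.0265). With all 7 libraries the groups overlapped for Areg. Lymphatic markers had a median of -0.52 over 4 genes (camera adjusted p = 0.0328; adjusted p = 0.412 with an estimated correlation). Adjusted over the list alone, Lyve1 (12.4 ± 3.92 to 4.49 ± 0.80 FPKM) and Pdpn (25.9 ± 2.77 to 14.3 ± 1.91) fell, as both did over all genes against wild-type replicates 1 and 2, where the median was -0.65. Of the other lymphatic members, Reln was lower by -0.23 and Flt4 higher by 0.13, and neither passed. The 16 genes of the growth hormone and insulin-like growth factor axis were not called as a list (median -0.21, camera adjusted p = 0.107). Adjusted over the list alone, 7 of them fell, including the receptor gene Ghr (136.7 ± 92.1 to 41.1 ± 6.50 FPKM), Igf1 (28.2 ± 18.1 to 8.51 ± 1.15) and Igf2 (27 ± 7.38 to 14 ± 0.06), and 2 rose, including Igfals, the acid-labile carrier subunit (38.2 ± 8.98 to 64.6 ± 2.73). Against wild-type replicates 1 and 2, Igf2 fell and Igfals rose over all genes, and Ghr (-0.99, adjusted p = 0.0711) and Igf1 (-0.79, adjusted p = 0.0934) did not pass.

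Genes of cholesterol synthesis were lower, with a median of -0.42 over 18 genes (camera adjusted p = 0.00190; adjusted p = 0.650 with an estimated correlation). Adjusted over the list alone, 6 fell, among them Msmo1 and Mvk. The median was -0.17 against wild-type replicates 1 and 2. Fatty acid and triglyceride synthesis went both ways (median 0.09, camera adjusted p = 0.946). Adjusted over the list alone, 5 of its 24 genes rose, including the lipogenic transcription factor Srebf1 (69.9 ± 21.2 to 130.4 ± 6.69 FPKM) and the elongase Elovl1 (36.3 ± 3.42 to 54.4 ± 7.56). The 3 that fell were Dgat2 (302.9 ± 147.5 to 100.7 ± 23.4), Dgat1 and Insig1. Proliferation genes had a median of -0.23 with 23 of 26 lower (camera adjusted p = 0.00570, and 0.791 with an estimated correlation). Their median was -0.29 against wild-type replicates 1 and 2, and none of them passed when adjusted over the list alone. The proliferation score of wild-type replicate 4 (-0.247) lay below those of the mutant libraries (-0.182 to -0.099). Wild-type replicates 1 to 3 lay above them, at 0.045, 0.360 and 0.244.

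**Figure D4:**
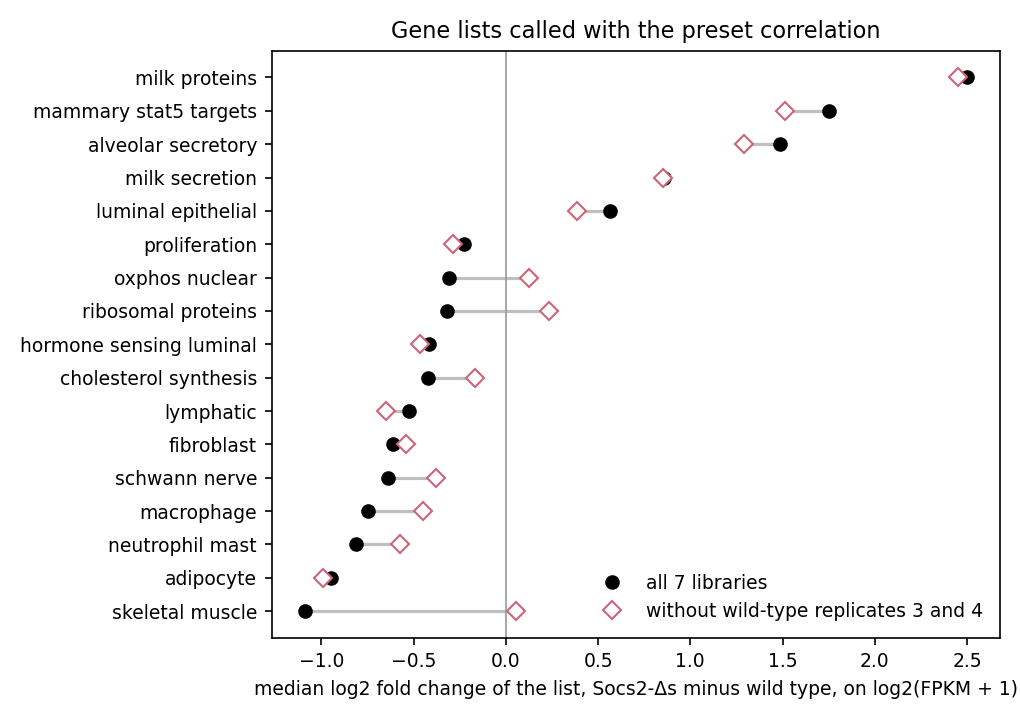
Median log2 difference (Socs2-Δs minus wild type, on log2(FPKM + 1)) of the 17 lists called with the preset correlation, with all 7 libraries (filled circles) and without wild-type replicates 3 and 4 (open diamonds). Milk proteins lie at 2.50 and 2.45 and adipocyte markers at -0.95 and -0.99, whereas ribosomal proteins change from -0.32 to 0.23.

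For 3 further lists the pooled call depended on wild-type replicates 3 and 4. Ribosomal protein genes had a median of -0.32 with all libraries (78 genes, camera adjusted p = 0.00450; adjusted p = 0.918 with an estimated correlation) and of 0.23 without those replicates (camera adjusted p = 0.00800; adjusted p = 0.839 with an estimated correlation), and the direction of the test also turned with quantile normalization. Nuclear genes of oxidative phosphorylation went from -0.31 (26 genes, camera adjusted p = 0.0151; adjusted p = 0.892 with an estimated correlation) to 0.12 (camera adjusted p = 0.185). Skeletal muscle genes went from -1.09 (14 genes, camera adjusted p = 0.0418; adjusted p = 0.864 with an estimated correlation) to 0.05 (camera adjusted p = 0.893). The markers of neutrophils and mast cells (median -0.81, camera adjusted p = 0.00500; adjusted p = 0.531 with an estimated correlation) and of Schwann cells and nerve (-0.64, 0.0232; adjusted p = 0.667 with an estimated correlation) completed the 17 called lists. Their medians were -0.57 and -0.38 without wild-type replicates 3 and 4. Retnlg fell in the former and the myelin gene Pmp22 in the latter, adjusted over each list alone with 7 libraries. None of the 17 calls held with an estimated correlation. B cell genes were high in wild-type replicate 4 and mutant replicate 2, with scores of 2.11 and 1.87 against -0.99 to -0.46 in the other 5 libraries, and T and natural killer cell genes followed them, with scores of 1.52 and 1.53. The B and plasma cell list (median 0.06, camera adjusted p = 0.836) and the T and natural killer cell list (0.03, 0.801) were not called.

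The remaining lists showed no group difference with this test. Camera adjusted p was 0.0898 for major histocompatibility complex class II genes (median -0.57), 0.204 for immediate early genes (-0.19), 0.432 for heat shock genes (-0.10), and 0.503 both for endothelial markers (-0.09) and for genes of the unfolded protein response (-0.18). It was 0.769 for basal and myoepithelial markers (0.04), 0.801 both for interferon response genes (-0.04) and for glucocorticoid targets (-0.09), 0.935 for genes of STAT3 and involution (-0.07) and 0.961 for brown adipocyte genes (-0.02). In the basal list, Procr, the protein C receptor, fell when adjusted over the list alone (14.4 ± 1.17 to 6.32 ± 1.18 FPKM), as did the transcription factor gene Klf4 in the immediate early list (12.6 ± 1.54 to 7.73 ± 0.43). The series also holds 5 ChIP-seq samples (STAT5 and H3K27 acetylation at pregnancy and lactation, glucocorticoid receptor at pregnancy, all in mutant glands) and 4 DNase-seq samples (wild type and mutant at pregnancy and involution). They were not analysed here, so nothing is reported on STAT5 binding or open chromatin at Socs2.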

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

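Of the tests in this part, the comparisons with transcripts of other tissues, nuclear RNAs and luminal markers, the question of stage, the splits of 5 libraries and the count of splits that keep wild-type replicates 3 and 4 together were chosen after the results were seen. So was the comparison of wild-type replicates 3 and 4 with the other 5 libraries. The splits of 7 libraries, the scaling test and the test of Y-linked genes were set beforehand.

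Among 89 sets of wild-type values (named genes, list scores and library totals), 7 had a library far from the other 3, measured as its gap to the nearest over the whole range; chance gives about 1 in 20 such sets. Wild-type replicate 4 was the library in 5 of them. It was lowest for Chrdl2 (gap ratio 0.834; log2(FPKM + 1) of 0.36 against 2.12 to 2.47), for Lalba (0.878; 1.93 against 3.48 to 3.70), for the basal and myoepithelial score (0.919) and for the lymphatic score (0.880), and highest for the B and plasma cell score (0.849; 2.11 against -0.91 to -0.46). Wild-type replicate 3 was lowest for the score of STAT5 targets shared by many tissues (0.844) and highest in recovered reads (0.844; 24.5 M against 21.3 to 21.8). This measure was not applied to the 3 mutant libraries.

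Of the 35 splits of the 7 libraries into 4 and 3, only the real split (1 of 35) called as many as 6 genes, and the highest of the others called 1. Chance division can be excluded for that count only if the 7 libraries are exchangeable, which wild-type replicates 3 and 4 put in doubt. Only 15 splits keep these replicates together, too few for a share under 0.05; among them the real split called 6 genes and the highest other 0, and the fit with a term for these replicates called 0. At an unadjusted p under 0.05, 3 of the 15 gave more genes (3166 to 3698) than the real split (2424), each with wild-type replicates 3 and 4 in the group of 3. Of the 10 splits of the 5 libraries without wild-type replicates 3 and 4, the real split (1 of 10) called 284 genes and the highest other 0; with 10 splits no share under 0.05 can be reached.

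Milk protein genes were higher in the mutant libraries, with a median log2 difference of 2.50. A shift in scaling by abundant transcripts is excluded as the whole cause, because the median was 2.71 after scaling without the 50 most abundant genes (camera adjusted p = 1.26e-09). The median of all genes was 0.179 with that scaling and -0.004 without it, so 2.71 is not a stronger rise relative to other genes. A larger share of luminal cells would raise pan-luminal markers alike, and the values argue against it as the whole cause. The milk protein score minus the luminal score was higher in mutant glands by 2.18 (exact two-sided permutation p = 0.0286, the smallest possible), and by 2.22 against wild-type replicates 1 and 2. That p takes the 7 libraries as exchangeable. A larger luminal share as part of the cause is not excluded, since 15 of the 16 pan-luminal markers were higher, with a median of 0.56. A larger share of alveolar cells within the luminal compartment, or a later functional stage of the mutant glands at the labelled day 13, may remain and cannot be told apart from an effect of the genotype, because no independent measure of stage is in hand. Purchased wild-type mice are a further untested difference between the groups.

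Wild-type replicates 3 and 4 differed from the other 5 libraries in 5217 genes. These 2 libraries were picked because they stood apart in the same values, so a high count follows from the choice. It cannot be set against the counts for genotype. RNA or reads of another tissue are excluded as the whole cause, because added RNA cannot remove transcripts, and Neat1 was lower there by a log2 difference of -5.18 and Firre by -4.81. The 8 nuclear-retained RNAs with a mean of at least 1 FPKM were all lower in mean log2 value (median -1.16). In wild-type replicate 3, Gas5 (138.6 FPKM) and Rian (7.77) still lay within the range of the other 5 libraries (91.6 to 147.4 and 5.15 to 20.1). The median of all 9 detected, Kcnq1ot1 included, was -0.986, short of the bound of -1. Another RNA or library preparation is a candidate explanation: small nucleolar RNA rows differed by a median of -2.08, whereas wild-type replicates 1 and 2 lay within -0.06 of the mutant libraries. Whether male animals contributed stayed open, since 0 Y-linked genes met the preset bounds although 2 exceeded 0.1 FPKM. Ddx3y measured 0.65 and 0.35 FPKM in wild-type replicates 3 and 4, and 0.19 to 0.41 in the other 5 libraries. Eif2s3y measured 0.19 and 0.06 FPKM in wild-type replicates 3 and 4, and 0.00 to 0.10 in the other 5. As Ddx3y exceeded 0.1 FPKM in all 7 libraries, the bound against male animals, every gene under 0.1 FPKM, was out of reach. No other biological explanation was tested.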

How the results depend on the processing

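The count of changed genes depended on the processing, while the directions of the named groups mostly did not. The fits without wild-type replicates 3 and 4, without wild-type replicate 4 and mutant replicate 2, with a term for wild-type replicates 3 and 4, and with voom were chosen after seeing the data. Against 6 genes, all higher, 1 gene (higher) was called with a pseudocount of 0.1 or with no filter, 0 with a mean of at least 5 FPKM (unadjusted p under 0.05: 901 higher, 898 lower), 28 with quantile normalization (25 higher, 3 lower), 10 (all higher) with scaling without the 50 most abundant genes, 1371 with library weights (635 higher, 736 lower), 284 without wild-type replicates 3 and 4 (189 higher, 95 lower), 0 without wild-type replicate 4 and mutant replicate 2, 3 (all higher) with voom on recovered reads, and 0 with the term for wild-type replicates 3 and 4 (787 higher and 902 lower at an unadjusted p under 0.05). The replicate number as a replicate block gave 0 genes (2085 at an unadjusted p under 0.05) and 0 higher, with 2 residual degrees of freedom; deviations of same-numbered libraries correlated by 0.35, -0.10 and 0.28, so the numbers were not taken as pairs, although 3 of 3 mutant and 2 of 3 wild-type libraries correlated best with their own number. Leaving out 1 library in turn gave 0 to 31 genes (0 to 31 higher, 0 to 1 lower). The fits without wild-type replicates 3 and 4 and with a term for them estimate the same log2 differences for a gene. Their counts of 284 and 0 thus differ through the residual spread, its degrees of freedom and the genes tested. The cause of the other shifts was not tested, apart from the fewer libraries or genes that some settings have by construction. Scaling without the 50 most abundant genes moved the median of all genes to 0.179, so its log2 differences are read relative to that. Socs2 was lower under all 22 alternatives (-0.60 to -0.26; adjusted p = 0.0201 to 0.592) and passed only with library weights (-0.604); leaving out 1 library gave -0.60 to -0.38. Of the 6 called genes all stayed higher under each alternative that tested them. Each passed under only 9 to 12 of its 21 or 22 alternatives, and its highest limma adjusted p was 0.355 to 0.396. The 17 called lists became 0 with an estimated correlation and 5 with fry (milk proteins, milk secretion, hormone-sensing luminal, lymphatic and fibroblast), and 14 to 18 with 1 library left out. The lists of adipocyte, alveolar secretory, cholesterol synthesis, fibroblast, hormone-sensing luminal, luminal epithelial, macrophage, mammary STAT5 target, milk protein and milk secretion genes kept direction and call under all other alternatives.

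Direction turned as follows, with the log2 difference or list median under that alternative; a list's sign is that of its test and can differ from that of its median. The cause was not tested, and none of these genes, and of these lists only ribosomal proteins, oxidative phosphorylation and skeletal muscle, had passed. Without wild-type replicates 3 and 4, and with the term for them, values were 0.99 for B and plasma cells, 0.124 for oxidative phosphorylation, 0.23 for ribosomal proteins, -0.008 for the SOCS family, -0.137 for Cep83, -0.003 for Eea1, 0.16 for Nudt4, 0.285 for Plxnc1, 0.145 for Prlr and 0.033 for Tmcc3. Without wild-type replicate 4 and mutant replicate 2 they were -0.14 for STAT3 and involution, -0.275 for T and natural killer cells, 0.074 for Prlr and 0.031 for Tmcc3. With library weights they were 1.69 for B and plasma cells, 0.054 for brown adipocytes, -0.14 for class II genes, 0.054 for ribosomal proteins, 0.655 for skeletal muscle, 0.051 for the SOCS family, 0.071 for Bcl6, -0.12 for Cep83, -0.046 for Eea1, 0.20 for Nudt4 and 0.59 for Plxnc1. The B and plasma cell list was called with these weights (camera adjusted p = 0.0237). With a mean of at least 5 FPKM they were -0.004 for STAT3 and involution and -0.109 for T and natural killer cells, as genes under the minimum left the lists. Brown adipocytes gave -0.125 with no filter, -0.021 without variance trend, -0.023 with quantile normalization, 0.17 with scaling without the 50 most abundant genes and -0.006 with voom. With quantile normalization, basal markers gave 0.155, glucocorticoid targets -0.072, ribosomal proteins 0.027, STAT3 and involution 0.008, the unfolded protein response -0.022, Eea1 -0.057 and Nudt4 0.008. With the replicate block, B and plasma cells gave 0.91, Bcl6 0.021, Cep83 -0.007, Eea1 -0.035 and Plxnc1 0.20. With scaling without the 50 most abundant genes, fatty acid synthesis gave 0.30, glucocorticoid targets 0.12, the SOCS family 0.15, T and natural killer cells 0.16, Bcl6 0.035, Nudt4 0.011, Plxnc1 0.11, Prlr 0.10, Socs3 0.075 and Tmcc3 0.055, all less than the shift of all genes apart from fatty acid synthesis. With voom, fatty acid synthesis gave 0.10. Leaving out 1 library gave, where a direction turned, these ranges: Prlr (-0.183 to 0.020), Bcl6 (-0.280 to 0.040), Eea1 (-0.038 to 0.064), Plxnc1 (-0.36 to 0.20) and Cep83 (-0.007 to 0.31), and the lists of the SOCS family (-0.062 to -0.008), glucocorticoid targets (-0.26 to -0.005), fatty acid synthesis (-0.185 to 0.201), basal (-0.153 to 0.078), brown adipocyte (-0.30 to 0.17), endothelial (-0.298 to 0.078), T and natural killer cell (-0.74 to 0.66), B and plasma cell (-0.91 to 0.94), interferon response (-0.325 to 0.253) and STAT3 and involution genes (-0.117 to 0.026).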

Other observations

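The tests in this part were chosen after the values were seen, except for the gene lists, which were written before the data were examined.

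The comparison with wild-type replicates 1 and 2 brought out gene groups that the 7 libraries together did not. Endothelial markers had a median log2 difference of -0.32 (14 genes, camera adjusted p = 7.50e-04; adjusted p = 0.513 with an estimated correlation), against -0.09 with all libraries. Immediate early genes had a median of -0.29 (camera adjusted p = 0.0135; adjusted p = 0.513 with an estimated correlation) and basal and myoepithelial markers of -0.22 (camera adjusted p = 0.0439; adjusted p = 0.683 with an estimated correlation), with Procr falling over all genes (-1.05, adjusted p = 0.0365). The growth hormone and insulin-like growth factor axis was lower as a list (-0.24, camera adjusted p = 0.00600; adjusted p = 0.513 with an estimated correlation). Interferon response genes were lower by a median of -0.33 (camera adjusted p = 0.0368; adjusted p = 0.839 with an estimated correlation). That call rested on wild-type replicate 2, whose score was 0.811, because the score of wild-type replicate 1 (-0.281) lay below those of all 3 mutant libraries (-0.229 to 0.259). The basal and myoepithelial call rested on mutant replicates 2 and 3, with scores of -0.085 and -0.097. Mutant replicate 1 (0.189) lay close to wild-type replicates 1 and 2 (0.191 and 0.211) in that score.

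Lymphoid genes separated 2 libraries across the genotypes. Cd79a, the B cell receptor component, measured 58.7 FPKM in mutant replicate 2 and 90.4 in wild-type replicate 4, and 0.61 to 1.1 in the other 5 libraries. Ms4a1, which encodes CD20, measured 14.5 FPKM in mutant replicate 2 and 37.9 in wild-type replicate 4, and 0.06 to 0.39 in the other 5 libraries. Leaving both libraries out gave 0 changed genes of 13260 tested, with 534 higher and 632 lower at an unadjusted limma p under 0.05.

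Cel, written down as a marker of exocrine pancreas for the search for foreign tissue, measured 33.3 to 46.1 FPKM in the mutant libraries, 10.5 and 13.0 in wild-type replicates 1 and 2, and 7.17 and 1.92 in replicates 3 and 4. The pancreatic genes Pnlip, Clps and Ctrb1 were listed at 0.00 in all 7 libraries. Cela1 of the same list measured 23.0 FPKM in wild-type replicate 4 and 2.01 to 4.97 elsewhere, and its other members did not exceed 0.30.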
